A study of Homo sapiens with 3 samples.

How the data were processed

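The data were counts of polyadenylated RNA 3′ ends in HEK293T cells, an established human embryonic kidney cell line. The assay was 2P-seq, which reads the junction of an mRNA with its poly(A) tail, and 4sU-2P-seq, its use on RNA captured through the nucleoside analogue 4-thiouridine (4sU). RNA made while 4sU is in the medium carries the analogue, so captured RNA is enriched for newly made molecules. There were 3 libraries, each the only library of its group: RNA captured after 30 min of labelling, RNA captured after 60 min, and the input of the 30 min labelling. Per the labels, the input stands for steady-state RNA; its treatment field reads none although its title names the 30 min labelling. No separate input of the 60 min labelling was used here.

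Per the labels' protocols, total RNA was poly(A) selected with oligo(dT) beads, cut lightly with RNase T1, selected again, reverse transcribed from an anchored oligo(dT) primer, size selected, circularised and amplified. Per the same protocols, the 4sU libraries skipped the initial poly(A) selection. Whether the input skipped it is not given in the sources used here. Each difference between a 4sU library and the input can therefore hold an effect of that step, or of the capture itself, besides the age of the RNA. Per the submitters' processing notes, cutadapt and Bowtie were used; their versions and roles, the genome build, and the handling of reads that map to several places are not given in the sources used here.

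The deposited values are raw counts of reads at single genomic positions, with strand, in 1 table per library and without normalization by the authors. The tables have no header. All values were whole numbers, and the libraries summed to 14159691 counts for 4sU 30 min, 8926568 for 4sU 60 min and 35410931 for the input. The protocol names no molecular identifiers, so reads of amplified copies are not independent molecules. Intervals of counts, ratios and shares, and floors, cover counting error only.

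The genome build was examined from the positions. Counts on chromosome 1 reached position 249223263, and 263 positions lay beyond the last gene of the GRCh38.p14 gene table at hand. Only 2.30% of sites lay within 50 nt of a gene boundary of that table, against 0.636% and 0.544% after moving every site by 10000 nt in either direction. The positions are therefore not those of GRCh38. No annotation or sequence of another build was used here, so no position was assigned to a gene, exon or untranslated region. The comparisons planned per gene, the gene lists and cell markers fixed before the data were examined, the annotation classes, and the analyses of poly(A) signals, RNA folding and internal priming were not run, and none of those lists gave a result. Sites took the place of genes, as a choice made after the data were seen. Positions are printed 1-based in the numbering of the deposited tables, whose build has no name in the sources used here. The strand was taken as that of the RNA, which the sources do not state; upstream and downstream would trade places if it were the opposite strand.

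Positions on the same strand within 24 nt of a local maximum of the summed counts were merged into a site. Counts were scaled to CPM of nuclear counts, with the mitochondrial genome (chrM) kept apart. The nuclear totals were 9652023 counts for 4sU 30 min, 6151986 for 4sU 60 min and 32768468 for the input. Nuclear sites with a mean CPM over the 3 libraries of at least 10 were compared, which left 10843 sites. For each, the ratio of the CPM values was given with an exact 95% interval of a ratio of 2 Poisson counts (Clopper-Pearson on the share). A site was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. A count of 0 was put at a floor of 3 counts per library. With 1 library per group there was no test across replicates, and no p-value is given. The rule for named items, fixed for genes and used here for sites, took the 10 highest and 10 lowest ratios among sites with a mean CPM of at least 30 and at least 20 counts in a compared library; the outermost of these are printed and the rest are summarised. Abundant sites and chrM sites were chosen after their values were seen.

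For alternative 3′ ends, neighbouring sites of a strand with gaps of at most 2000 nt formed a group. Sites needed at least 20 counts and 5% of the group, and groups at least 100 counts. The share of a group's counts at its outermost downstream site was compared between libraries. A group was called shifted at a change of at least 10 percentage points with a 95% interval of the difference (Newcombe) that excluded 0. Gaps of 500, 1000, 2000 and 5000 nt had all been seen before 2000 nt was taken. Groups can join ends of different genes. Among sites with a mean CPM of at least 30, the mean position and the standard deviation (SD) of positions within each site were compared; this filter replaced an earlier one on counts in every library. Shares carry Wilson 95% intervals. Medians carry 95% percentile intervals from 1000 bootstrap draws over sites or groups, and from fewer draws where settings were varied. The intervals of medians give the uncertainty of a median over the sites or groups of these libraries, not the spread among single ones. They treat neighbouring sites as independent. Medians of chromosomes were set beside 10000 random lists of sites of the same size matched on mean CPM. These lists drew sites singly and so also treat neighbouring sites as independent. The chromosome and 1 Mb window comparisons, the 16-fold limit, the 90% limit on counts at 1 position, the 10000 nt distance for isolated sites, the 8-fold limit of the rank correlation and the 1% limit for chrM sites were set after the data were seen.

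To compare the ratio of 60 to 30 min with that of 30 min to input, the 30 min counts were split at random in equal parts, so that the ratios shared no 30 min counts. Parts of 1 library still share its molecules and any deviation of that library, so sites were also classed by the ratio of 60 min to input, with the 60 min counts split; this was chosen after the data were seen. Agreement of the 4sU libraries against their shared input was set beside simulated unchanged libraries. Alternatives were median-of-ratios and TMM scaling, CPM with chrM counts, other filters, thresholds, merging windows and gaps, thinning, and leaving out sites with at least 90% of counts at 1 position. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9; edgeR 4.0.16 in R 4.3.3 gave the TMM factors only.

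The steps were tested on simulated data drawn from the real site means and depths, with counting error only. Amplified copies and variation between libraries were not simulated, so calls of unchanged sites there do not measure false calls in the real data. For 4sU 30 min against input, 100% of 100 sites changed 3-fold were called and 1% of those changed 1.5-fold, and 0 of 10643 unchanged sites were called. For 4sU 60 min against input the shares were 100% and 1%, and for 60 against 30 min 99% and 0%. Of the groups moved by 20 points between 4sU 30 min and input, 85% were called, with 168 of 7537 unchanged groups called.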

Results

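The series asks how structures at the 3′ ends of mammalian mRNAs bear on mRNA processing and stability, and this data set compares newly made with steady-state RNA ends in HEK293T cells, an established human embryonic kidney cell line. RNA labelled with 4-thiouridine (4sU) for 30 or 60 min was captured, and its poly(A) ends were sequenced beside those of the input RNA. The tables held 862705 positions with counts in 4sU 30 min, 655861 in 4sU 60 min and 1027373 in the input, with totals of 14159691, 8926568 and 35410931 counts. Each group had 1 library (n = 1), so no difference below has a replicate check, and intervals of ratios and shares cover counting error only. Intervals of medians are bootstraps over sites or groups. They show how firmly these sites or groups place the median, not the spread among single ones and not the variation between replicates. Sites are given by chromosome, position and strand in the numbering of the tables; the build is not named in the sources used here, and genes were not assigned.

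Among 10843 nuclear 3′ end sites, 3823 were at least 2-fold higher in 4sU 30 min than in input, 1859 were at least 2-fold lower and 5161 were neither. The question was which RNA ends are over-represented among RNA made within 30 min. The sites called higher held 33.2% of nuclear 4sU counts and 8.37% of nuclear input counts. The sites called lower held 13.96% and 44.1%. At least 4-fold differences were seen at 1973 higher and 369 lower sites.

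Among sites with a mean CPM of at least 30, the highest ratio was at chr12:81839019 on the plus strand, with 2890 counts in 4sU 30 min and 7 in input, or 1402-fold (679 to 3489). The next, chr20:26189024 on the minus strand, had 326 counts against 1 in input, a ratio of 1107 with an interval from 197 to 43847. The 10 highest sites ranged from 222- to 1402-fold. Another 13 sites of lower mean CPM had 0 counts in input, so their ratios are bounds and were not ranked. Among the lowest of the sites with a mean CPM of at least 30, chr12:76443347 on the minus strand was 13.4-fold lower (11.4 to 15.9) and chr11:118886421 on the minus strand was 11.4-fold lower (8.95 to 14.7). The 10 lowest ranged from 7.71- to 13.4-fold.

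Of the most abundant sites, chr20:3764500 on the minus strand took 3.83% of nuclear counts in 4sU 30 min (3.81 to 3.84) against 1.103% in input, 3.47-fold higher. The site at chr2:217366183 on the plus strand took 0.218% against 1.25%, 5.73-fold lower. The sites at chr12:49521569 on the minus strand and chr12:6647536 on the plus strand lay within 2-fold of the input, at 0.880% against 0.973% and 0.508% against 0.704%. The median log2 ratio of all sites was 0.37. For sites with a mean CPM of at least 50 it was 0.0445, with 839 sites called higher and 679 lower. The balance of calls thus depended on the filter, and it also depended on the scaling. Higher sites made up 67.3% of the calls with nuclear CPM, 53.1% with median-of-ratios scaling (3063 higher, 2704 lower), 52.4% with TMM (3022 and 2750) and 50.2% with chrM counts in the total (2922 and 2898).

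After 60 min of labelling, 2963 sites were at least 2-fold higher than in input, 2361 were lower and 5519 were neither. The site at chr12:81839019 on the plus strand was again the highest among sites with a mean CPM of at least 30, with 4692 counts against 7 in input, or 3570-fold (1731 to 8885). At chr8:15060464 on the plus strand, also in this set, 506 counts stood against 1 in input, a ratio of 2695 with an interval from 482 to 106663; 100% of the counts at this site lay at 1 position. The lowest ratios in this set were at chr7:26231467 on the minus strand, 11.6-fold lower (10.5 to 12.95), and chr21:26957970 on the minus strand, 11.5-fold lower (8.70 to 15.5).

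The abundant site at chr20:3764500 on the minus strand rose further, to 6.94% of nuclear counts (6.92 to 6.96), 6.29-fold its share in input. The site at chr2:217366183 on the plus strand held 0.485%, 2.58-fold below the input. Higher sites were 55.7% of the calls with nuclear CPM and 38.2% (2172 higher, 3508 lower) with chrM counts in the total. They were 52.7% with median-of-ratios scaling (2828 and 2537) and 51.1% with TMM (2753 and 2631). The 30 min input was the reference here too, as no input of the 60 min labelling was used.

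The 4sU libraries ranked the sites alike against the input. Across sites, the log2 ratios at 30 and 60 min had a Pearson r of 0.917 and a Spearman rho of 0.9002. In simulated unchanged libraries, with a simulated input shared by both ratios, these were 0.190 and 0.176. The covariance of the ratios was 2.95, against 0.0031 in the simulation, a difference of 2.95. In both libraries 2713 sites were higher and 1473 were lower, against 1045 and 405 for independent lists of the same sizes. Sites are not independent replicates, and part of the excess may come from the shared input library. The 4sU libraries also share the capture and the skipped initial poly(A) selection, which the simulation did not include.

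**Figure D1:**
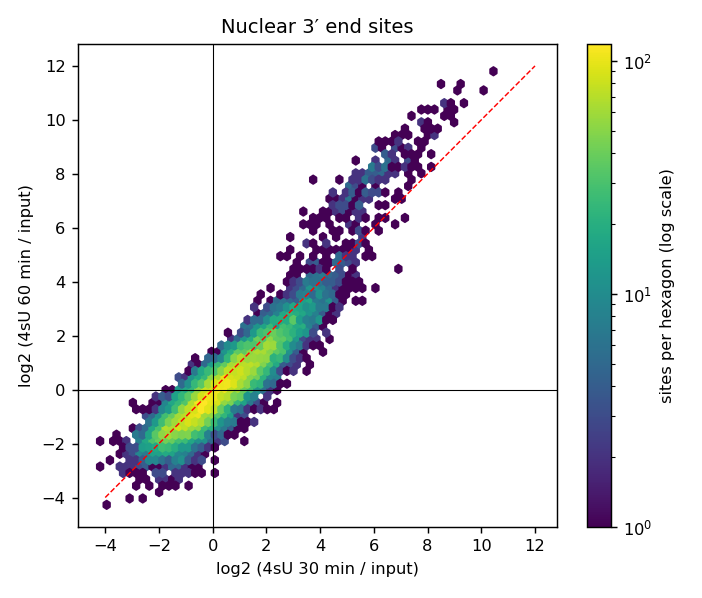
Log2 ratio of each of the 10843 nuclear sites to the input, with 4sU 30 min on the horizontal and 4sU 60 min on the vertical axis; colour gives the number of sites per hexagon on a log scale and the dashed line marks equal ratios. Most sites lie along the line (Pearson r = 0.917), with a separate arm above it among sites far higher in 4sU than in input.

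Between the labelling times, 497 sites were at least 2-fold higher at 60 than at 30 min, 1522 were lower and 8824 were neither. Among sites with a mean CPM of at least 30, the largest rises were at chr17:60176976 on the minus strand, 7.85-fold (7.10 to 8.70), and chr2:96870292 on the plus strand, 7.09-fold (5.92 to 8.53). Of the counts at these sites 99.5% and 97.0% lay at 1 position. The largest falls in this set were at chr6:43608677 on the plus strand, 7.47-fold (5.92 to 9.56), and chr16:96987 on the minus strand, 6.06-fold (4.75 to 7.84). Larger falls occurred at sites of lower mean CPM, such as chrX:13727789 on the plus strand, from 41.0 to 4.55 CPM, chosen after its values were seen. The abundant sites at chr20:3764500 and chr2:217366183 were 1.81- and 2.23-fold higher at 60 min. The direction of most calls turned with median-of-ratios scaling and TMM, but not with chrM counts in the total. Higher sites were 24.6% of calls with nuclear CPM, 55.0% with median-of-ratios scaling (897 higher, 735 lower) and 53.1% with TMM (866 and 765). With chrM counts in the total they were 25.9% (509 and 1458). The median log2 ratio was -0.27 with nuclear CPM and 0.033 with median-of-ratios scaling, so single sites are best read against the median.

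Classed by their ratio of 4sU 30 min to input, higher sites were, up to 16-fold, lower at 60 min relative to other sites, but not when classed by the ratio of 60 min to input. With separate parts of the 30 min counts in each ratio, the median log2 ratio of 60 to 30 min was 0.41 (0.33 to 0.46) for 371 sites more than 4-fold lower in 4sU 30 min than in input. It was -0.19 for 2575 sites between 2-fold lower and level, -0.61 (-0.64 to -0.57) for 1068 sites 4- to 8-fold higher and -0.555 (-0.650 to -0.489) for 482 sites 8- to 16-fold higher, against -0.269 for all sites. Across the 9944 sites under 8-fold, Spearman rho was -0.352; across the 886 sites from 8-fold, which pool the last class with the higher one described next, it was 0.505, and across all 10830 it was -0.269 (-0.275 without the split). With sites classed by the ratio of 60 min to input, which uses no 30 min counts, and the 60 min counts split instead, the median was -0.489 (-0.571 to -0.350) for 476 sites more than 4-fold lower and -0.301 (-0.352 to -0.241) for 712 sites 4- to 8-fold higher. Spearman rho was then 0.017 across 10190 sites under 8-fold.

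The 404 sites at least 16-fold higher broke this trend, with a median of 0.89 (0.37 to 1.20), but this depended on the filter. With a mean CPM of at least 50, 63 such sites had a median of -0.081 (-0.236 to 0.101), near the -0.108 of all sites in that set and above the -0.570 of its sites 4- to 8-fold higher. The 404 sites were split by the share of their counts, summed over all libraries, at their highest position. The 169 with at least 90% of their counts at 1 position had a median of 1.94 (1.85 to 2.02), and 78.1% of them had no other site of at least 20 counts within 10000 nt on the same strand. They held 0.271% of nuclear counts at 30 min, 0.934% at 60 min and 0.00497% in input. Such sites passed the filter on mean CPM more easily when high at 60 min, which can raise this median. The other 235 of the 404 had a median of -0.27 (-0.44 to -0.14), close to that of all sites. Of these, 31.1% were isolated by the same rule. Among the 10424 sites under 16-fold with all 30 min counts, 15.0% were isolated.

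**Figure D2:**
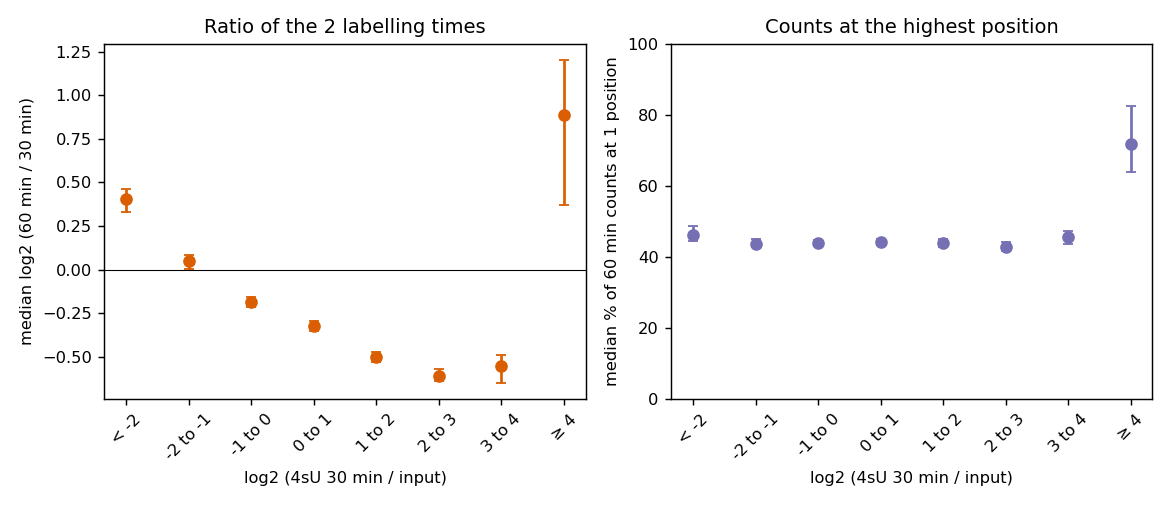
Sites grouped by their log2 ratio of 4sU 30 min to input (horizontal axes), with the median log2 ratio of 60 to 30 min on the left. On the right is the median percentage of a site's 60 min counts at the position highest in the 30 min library. Points are medians and bars 95% bootstrap intervals over sites. Both measures rise in the class of at least 16-fold, to 0.89 and 71.9%, with medians of 42.9 to 46.1% in the other classes on the right. Sites of that class with few 30 min counts passed the filter on mean CPM more easily when high at 60 min.

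Chromosomes differed in how far their sites were enriched in 4sU-captured RNA. Against input, the median log2 ratio at 30 min was highest on chromosomes 19 (0.81, 698 sites), 20 (0.76, 347 sites), 22 (0.71, 306 sites), 17 (0.70, 759 sites) and 16 (0.59, 536 sites). It was lowest on chromosome X (-0.16, 347 sites), followed by 18, 14 and 4 with 0.067, 0.079 and 0.088. On chromosome 19, 320 sites were called higher and 81 lower; the central 95% of random lists matched on mean CPM ran from 0.16 to 0.46. For chromosome X it ran from 0.12 to 0.54. At 60 min, chromosome 19 was again the highest, at 0.64, and chromosome 4 the lowest, at -0.31. Relative to all sites the 30 min medians of chromosomes 19 and X were 0.44 and -0.53, values that a common scaling factor does not move.

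Among windows of 1 Mb with at least 8 sites, the stretch of chromosome 19 from 58000001 to 59000000 had a median log2 ratio of 3.04 over 25 sites at 30 min, with 20 higher and 0 lower. Of its sites, 18 were higher and 0 lower at 60 min. The window of chromosome 1 from 234000001 to 235000000 reached 3.04 over 10 sites, and that of chromosome X from 119000001 to 120000000 was lowest at -1.68 over 9 sites. In 100 shuffles of sites among windows, the highest and lowest window medians were typically 2.38 and -1.01 (medians over shuffles) and at most 3.93 and -1.78, which none of the 454 windows passed. These extremes were not matched to the number of sites in a window. The chromosome 19 window lay above all of 10000 random lists of its own size at both times, with no adjustment for the number of windows examined. Those lists drew sites singly from all chromosomes, while sites of a window are neighbours and may be ends of the same genes. The 60 min ratio has the same input, so it is no separate check of a window picked at 30 min.

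**Figure D3:**
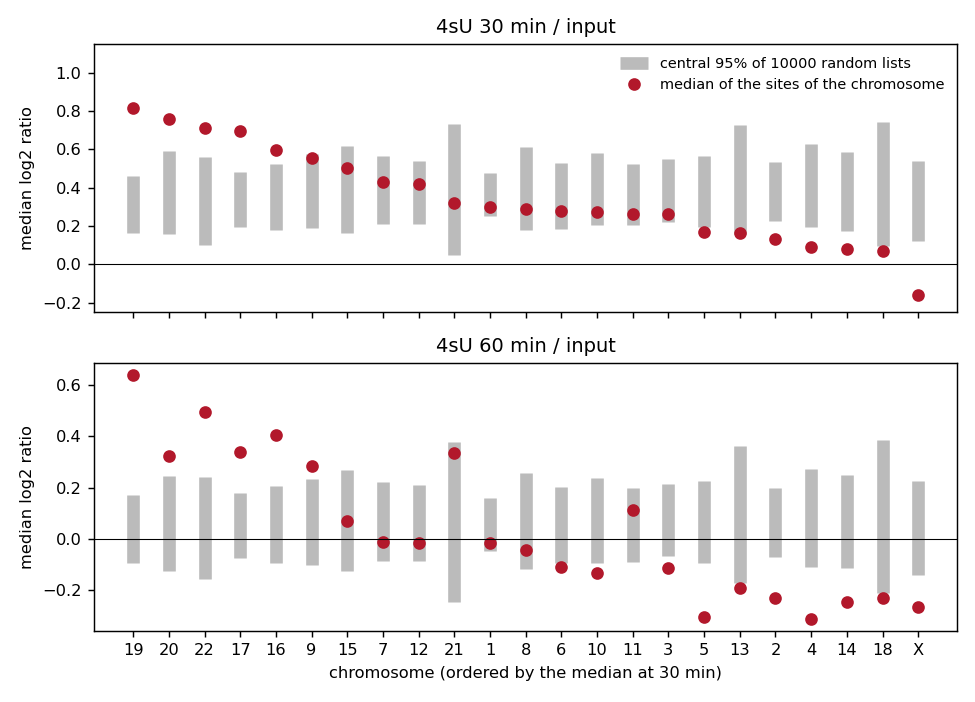
Median log2 ratio to input of the sites of each chromosome (red points) at 30 min (top) and 60 min (bottom), with grey bars for the central 95% of 10000 random site lists of the same size matched on mean CPM. Chromosomes 19, 20, 22, 17 and 16 lie above their bars in both panels and chromosomes 2, 4, 5, 14, 18 and X lie below theirs in both.

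Downstream ends of neighbouring 3′ ends took a larger share in the 4sU libraries than in the input. In 7737 groups of ends, the share of the outermost downstream end was at least 10 points higher in 4sU 30 min than in input in 1393 groups and lower in 814. At 60 min it was higher in 1497 and lower in 838. The median change was 1.67 points (1.41 to 1.92) at 30 min and 1.78 points (1.497 to 2.02) at 60 min. In a pair of ends on the minus strand of chromosome 5, at 126380911 (upstream) and 126380460 (downstream), the downstream end held 98.1% of counts in 4sU 30 min (154 of 157, 94.5 to 99.3) and 9.68% in input (3 of 31, 3.35 to 24.9). In a pair on the plus strand of chromosome 12, at 132199092 and 132199488, it held 99.6% (457 of 459) and 12.96% (7 of 54). On the minus strand of chromosome 10, at 75183339 and 75181970, the downstream end held 21.0% in 4sU 30 min (22 of 105) and 97.2% in input (1311 of 1349).

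The change grew with the distance between the outermost ends. At 30 min the median was 0.580 points in 3001 groups spanning under 500 nt, 1.64 from 500 to 1000 nt, 2.46 from 1000 to 2000 nt and 3.36 (2.67 to 4.02) in 1039 wider groups. At 60 min the first and last of these classes had medians of 0.125 (-0.450 to 0.519) and 5.01 points (4.03 to 5.86). From 30 to 60 min the median over all groups moved by 0.159 points (0 to 0.376), with 647 groups higher and 609 lower. This hid opposite moves: -0.407 points (-0.756 to -0.142) in groups under 500 nt, with 165 higher and 230 lower, and 1.79 points (1.22 to 2.44) in groups of at least 2000 nt, with 135 higher and 68 lower. With gaps of at most 500 nt the medians against input were 0.458 and 0.256 points, with 777 groups higher and 662 lower at 30 min and 777 and 699 at 60 min. From 30 to 60 min the direction then turned, to -0.284 points with 370 higher and 421 lower; with gaps of at most 1000 nt it was -0.029 points with 465 and 541. With gaps of at most 5000 nt the median from 30 to 60 min was 0.629 points, with 918 groups higher and 716 lower. Wider groups are more open to joining ends of different genes. Splitting the input at random gave a median of -0.012 points, with 98 groups higher and 82 lower. This split of 1 library shows counting error only, not differences that arise between libraries.

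**Figure D4:**
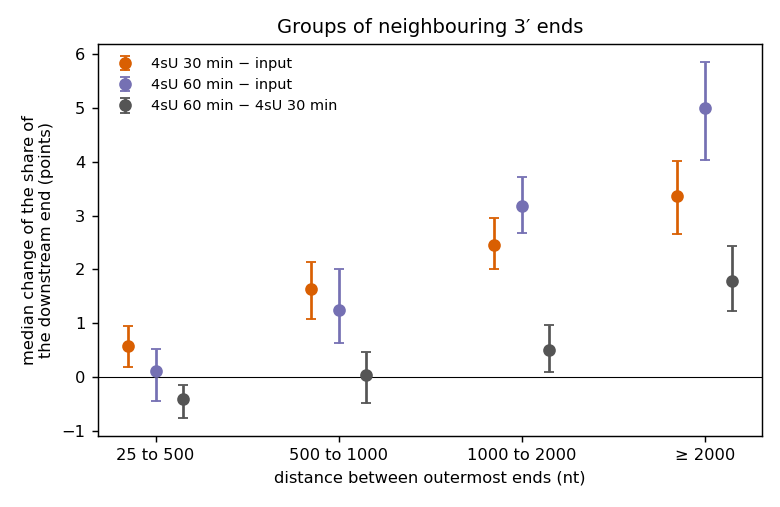
Median change in the share of the outermost downstream end (percentage points, vertical axis) for groups of neighbouring 3′ ends, by the distance between the outermost ends; colours mark the 3 library comparisons and bars are 95% bootstrap intervals over groups. The change against input rises with distance, from 0.580 to 3.36 points at 30 min and from 0.125 to 5.01 points at 60 min.

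Within single sites, counts in the 4sU libraries lay slightly upstream and were more spread. Over 4874 sites the mean position in 4sU 30 min lay upstream of that in input in 71.9% of sites, with a median difference of -0.117 nt (-0.125 to -0.111). At 60 min it lay upstream in 70.3%, with a median of -0.106 nt (-0.115 to -0.0996). The SD of positions was larger than in input in 70.1% of sites at 30 min and 59.2% at 60 min, by medians of 0.119 and 0.053 nt. Between 30 and 60 min the median shift was 0.0027 nt, with an interval that included 0 (-0.00079 to 0.0073). In a random split of the input, 48.6% of sites lay upstream and the median shift was 0.0013 nt.

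Mitochondrial 3′ ends made up 31.8% of all counts in 4sU 30 min (31.8 to 31.9) and 31.1% in 4sU 60 min, against 7.46% in input (7.45 to 7.47), or 4.27- and 4.17-fold the input. The minus strand held 15.8%, 15.2% and 44.5% of chrM counts in the order 30 min, 60 min and input. The 13 sites with at least 1% of chrM counts in a library differed widely in this rise. The site at chrM:3233 on the plus strand was 23.5-fold its share of the input library at 30 min (23.3 to 23.6) and 23.8-fold at 60 min, and chrM:5512 on the plus strand was 16.7- and 18.3-fold. The site at chrM:16027 on the minus strand was 15.4- and 21.4-fold. By contrast, chrM:221 on the minus strand, with 39.1% of chrM counts in input, was 1.29- and 1.09-fold, and held 11.9% and 10.2% of chrM counts in the 4sU libraries. The site at chrM:9991 on the plus strand fell between labelling times, from 10.4% to 4.71% of chrM counts. The 4sU libraries also skipped a poly(A) selection, which the labels do not state for the input.

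**Figure D5:**
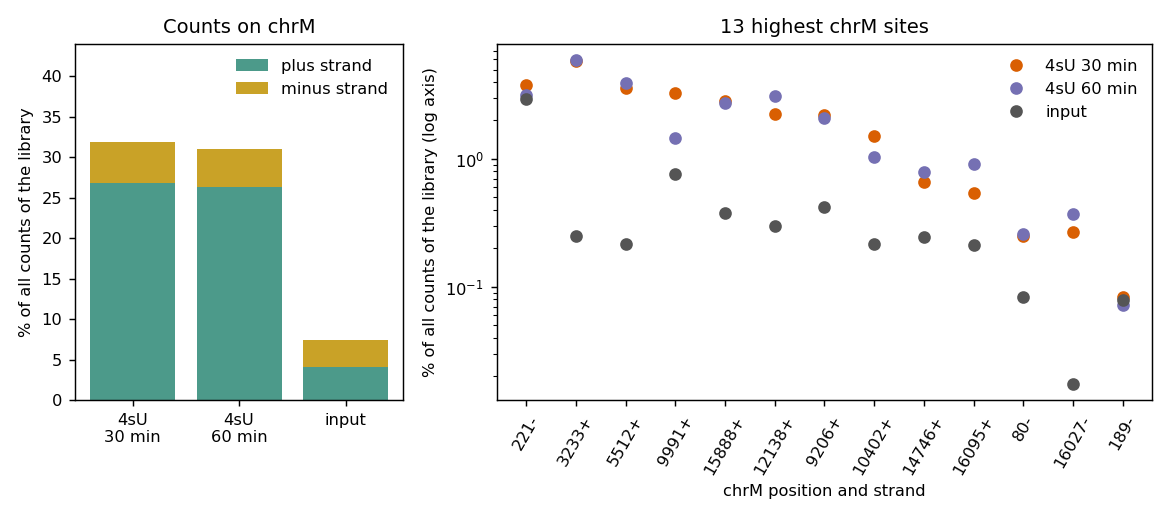
Left, percentage of all counts of each library on chrM, by strand; right, percentage of all counts of each library at the 13 highest chrM sites, on a log axis, by position and strand. The total is 31.8% and 31.1% in the 4sU libraries and 7.46% in input, and chrM:221 on the minus strand is nearly level while chrM:3233 on the plus strand rises 23.5-fold.

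Counts also spread over more low sites in the 4sU libraries. Nuclear sites below the filter held 18.1% of nuclear counts in 4sU 30 min, 17.2% in 4sU 60 min and 10.0% in input. Sites with fewer than 20 counts over the 3 libraries held 5.48%, 6.77% and 2.05%. After thinning to about equal nuclear totals these shares were 7.10%, 7.98% and 3.17%.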

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

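All tests of explanations in this part were chosen after the results were seen. Mitochondrial counts, which stayed outside the nuclear comparison, were 31.8% of the 30 min library and 31.1% of the 60 min library, above the 7.46% of the input. A rise carried by a few abundant sites as the whole cause was excluded: without the 13 highest chrM sites the share was still 4.46-fold that of the input at 30 min. Skipping the poly(A) selection in the 4sU libraries may have raised RNAs with short tails. The 4sU libraries, made alike, differed by 1.02-fold, but capture and the skipped selection occurred in the same libraries, so these cannot be told apart. Fast synthesis and turnover of mitochondrial RNA stays open as an untested biological explanation.

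Nuclear counts in sites below the filter, also outside the site comparison, were 18.1% at 30 min and 17.2% at 60 min against 10.0% in input.

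With nuclear CPM, at 7 sites the 30 min library was at least 2-fold above the input and the 60 min library at least 2-fold below it. This difference between labelling times was not tested beyond counting error. An example is chrX:13727789 on the plus strand, 2.35-fold higher at 30 min and 3.83-fold lower at 60 min, chosen after its values were seen.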

How the results depend on the processing

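The alternatives on merging windows for site counts, on leaving out sites with 90% of counts at 1 position throughout, the gaps of 500, 1000 and 5000 nt, the leaving out of chrM sites, and all alternatives for position spread, chromosomes and the 60 to 30 min trend were chosen after the data were seen; the others were planned. No paired analysis was possible because each group had 1 library. Of 116 alternative values for main counts and shares, 81 stayed within 1.5 times the main count or within the interval of the main value; of 71 values for medians, rank correlations and position measures, 34 did. The settings on assignment to genes, internal priming, sites within introns, folding windows, hexamers and gene lists were not run, for lack of an annotation and sequence of the build. The causes of the changes below were not tested, except where fewer or more sites entered by construction.

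In the order 30 min against input, 60 min against input and 60 against 30 min, the sites higher and lower were 51685 and 6816, 61505 and 7952, and 8535 and 9370 without the filter on low counts. With a mean CPM of at least 50 they were 839 and 679, 702 and 697, and 124 and 216. At 1.5-fold, 2814 sites were lower at 30 min against input, and 1149 were higher and 3408 lower at 60 against 30 min. Median-of-ratios scaling gave 897 higher and 735 lower at 60 against 30 min, and TMM 866 and 765. With chrM counts in the total, 2898 sites were lower at 30 min against input. Without sites with 90% of counts at 1 position, 320 were higher at 60 against 30 min. The Pearson r was 0.923 at a mean CPM of at least 50 and 0.908 with the input split in 2.

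The median log2 ratio changed sign at 30 min against input with TMM (-0.015) and with chrM counts (-0.070). At 60 min against input it changed sign with median-of-ratios scaling (-0.0056), TMM (-0.040), chrM counts (-0.36) and a mean CPM of at least 50 (-0.057). At 60 against 30 min it did so with median-of-ratios scaling (0.033) and TMM (0.017). The median of sites at least 16-fold higher fell to -0.081 (63 sites, -0.236 to 0.101) at a mean CPM of at least 50 and to -0.27 without sites with 90% of counts at 1 position. The Spearman rho of the 60 to 30 min trend (-0.352) turned to 0.017 with sites classed by the ratio of 60 min to input.

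Of groups, 533 had a lower downstream share at 30 min against input with at least 300 counts, and 890 had a higher and 519 a lower share after thinning. With gaps of at most 500 nt, 777 were higher and 662 lower against input at 30 min, 777 and 699 at 60 min, and 370 and 421 at 60 against 30 min, where more had been higher (647 and 609). The median change from 30 to 60 min turned to -0.284 points at 500 nt and -0.029 points at 1000 nt. At 5000 nt it rose to 0.629 points, with 918 groups higher and 716 lower. Against input (30 min, 60 min) the medians were 0.892 and 0.785 points at 1000 nt and 2.16 and 2.69 points at 5000 nt. The chrM shares (30 min, 60 min, input) were 32.99%, 32.5% and 7.58% over positions with at least 2 counts, and 6.47%, 7.06% and 1.45% without the 13 highest sites.

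In data simulated at the depths of these libraries, 99% or more of the tested sites changed 3-fold were called, so depth did not limit calls of that size among tested sites; a 1.5-fold change lies under the 2-fold limit by construction.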

Other observations

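All tests of explanations in this part were chosen after the results were seen. Sites at least 16-fold higher in 4sU 30 min than in input numbered 419 with all 30 min counts, and held 2.05% of nuclear counts at 30 min, 2.60% at 60 min and 0.0750% in input. Of them, 99.5% were also at least 4-fold higher at 60 min. The mean CPM filter includes the 60 min counts, so sites low at 30 min could enter only when high at 60 min. For such sites this share was fixed in advance, and amplification of single molecules in the 30 min library was not excluded. The 235 sites with under 90% of summed counts at 1 position held 1.77% of nuclear counts at 30 min and 1.62% at 60 min. They held 0.0704% in input. As a set, their rise was therefore not confined to the 30 min library. Of the 419 sites, 43.2% had at least 90% of 60 min counts at the position highest in the 30 min library, against 0.691% of other sites. Priming inside RNAs or RNA ends other than cleaved and tailed ones may account for that part. Those with at least 90% of summed counts at 1 position had a median 60 to 30 min log2 ratio of 1.94 (1.85 to 2.02). That lay above the -0.27 of all sites, where rapid turnover alone would put it below. With only 0.00497% of nuclear input counts, such sites passed the filter on mean CPM more easily when high at 60 min. Rapid turnover alone was therefore not excluded for them. For the others (-0.27, -0.44 to -0.14) the median did not decide. Without a genome sequence, priming and other RNA ends could not be separated.

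The fall of the 60 to 30 min ratio with the 30 min to input ratio was not counting error of reads alone, since with separate parts of the 30 min counts Spearman rho was -0.269 over all sites, against -0.275 without the split, and -0.352 over the sites under 8-fold. Deviations of the single 30 min library that all its reads share, such as those from amplification or capture, pass through this split and could give the fall. With sites classed by the ratio of 60 min to input, which uses no 30 min counts, rho was 0.0175 over sites under 8-fold, 0.121 over those chosen by an input CPM of at least 30 alone and -0.055 over those with a mean CPM of at least 50, so little or no fall was seen without the 30 min library in the classes. Deviations of the 60 min library would raise this rho, so it does not decide. The medians by the 30 min to input ratio spread by 1.02 on the log2 scale (0.94 to 1.08) between the lowest class and the class of 4- to 8-fold. RNAs of different lifetimes could give a spread of up to 1 under first-order decay, a bound inside that interval. The bound holds between RNAs barely replaced and RNAs fully replaced within 30 min. If enrichment at 30 min follows the share replaced, the 482 sites at 8- to 16-fold put the 4- to 8-fold class below full replacement. Lifetimes alone would then give less than 1, and little of the fall from 0.41 to 0.051 between the lowest class and the next. Unlabelled RNA making up 18.0% of the 60 min library, beyond that of the 30 min library, could give the full spread of these medians. Under that model a site's 60 min share stays at or above 18.0% of its input share. The 10 lowest sites with a mean CPM of at least 30 lay below this, at 8.14- to 11.6-fold under input. Carry-over of that size alone does not give these sites, which were picked as the lowest. How far each of these 3 explanations contributes cannot be told without replicate libraries and a measure of carry-over.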
